A study of Mus musculus with 4 samples.

How the data were processed

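The study sorted live CD45+ cells from PyMT mammary tumors and labeled the suspension of each tumor with its own TotalSeq-B hashtag antibody. The tumors of each group were pooled and profiled with 10x Genomics 3' version 3.1 chemistry, aiming at 10000 cells per sample and 50000 reads per cell. The series lists 4 samples, a gene expression and a hashtag library for each group. Per the file headers and the submitters' processing notes, the deposited values are raw UMI counts per gene and cell from Cell Ranger 7.1.0 on mm10, in 1 matrix per tumor with 32285 genes and 4 hashtags. The annotation release and the cell-calling settings are not given in the sources used here. The labels report no difference in tumor volume, which was not analysed here.

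Matrices of NTC tumors 1, 2 and 3 and Il1a-targeted tumors 2 and 3 were taken as 5 replicates. The hashtag assigned to a tumor led in every cell of its matrix, with medians of 2032, 3268, 2680, 4041 and 3661.5 UMIs against 57, 43, 56, 41 and 34 for the highest other hashtag. Matrices of a group shared 0 barcodes. In the order above, the matrices held 8756, 8554, 9403, 7532 and 19662 cells with 188420737, 198403656, 211907274, 149210086 and 519772685 gene UMIs. Cells with at least 200 genes and at most 15% mitochondrial counts were kept, which removed 146, 158, 163, 69 and 210 cells. Scrublet in scanpy then marked 593, 564, 683, 446 and 3027 cells as doublets at a rate set in proportion to the cells of a tumor (6.89%, 6.72%, 7.39%, 5.98% and 15.6% of cells), and these were removed. This rate is meant for doublets within a tumor. The tumors of a group shared a library, so the rate for the whole pool would be higher, as it also counts doublets across tumors. Whether the split by hashtag had removed all of those was not tested. Median UMIs per cell were 20043.5, 21051, 20915, 20815 and 24036 in monocytes and macrophages and 6979, 6237, 8035, 8603 and 8957 in T cells. The number of tumors limits the precision of all values.

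Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbors and Leiden clustering at resolution 1 with seed 0 gave 28 clusters, without batch integration. Clusters were named from fixed marker genes, needing at least 3 markers raised by 1.25-fold over the median cluster (4 for monocytes and macrophages), and 4 clusters stayed unnamed. T and NK clusters were clustered again into subsets. A subcluster with a median UMI count over 3 times that of T and NK cells was set aside as mixed, and Cd3e in at least 50% of cells ruled out an innate name. Classes with at least 20 cells in every tumor were tested, which left 6, holding 5902, 6271, 7161, 3781 and 13987 monocytes and macrophages, 625, 306, 657, 1687 and 1252 T cells, 172, 74, 78, 227 and 145 NK cells, 263, 210, 112, 142 and 224 DCs, 114, 151, 67, 82 and 53 neutrophils, and 56, 27, 32, 160 and 69 B cells. Coordinates were read from the GENCODE vM21 annotation of mm10, which held 32158 of the gene identifiers.

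Counts were summed per tumor and class and tested with the edgeR quasi-likelihood test after filterByExpr with TMM factors, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each class was fitted on its own, and all sorted cells once more together. CPM values of genes in a class are counts scaled to the total of the tested genes in a tumor, adjusted by its TMM factor. Sums of marker genes, the free RNA estimate, values within single clusters and the macrophage values set beside them use plain totals. The 20 gene lists were tested with camera of limma on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 118 tests of lists with at least 5 measured members. Of these, 65 passed, 31 higher and 34 lower. A list is said to pass, rise or fall by this preset test unless stated. Where members move together more than the preset correlation, its p-values are too small. Shares of cells and sums of marker genes were compared with an exact two-sided permutation test over the 10 splits of the tumors, and shares also with edgeR on cell counts.

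Free RNA was estimated from the summed counts of all cells of a group, scaled by the median ratio of C1qa, C1qb and C1qc in classes that should lack them, or of Cd3d, Cd3e, Cd3g, Trac, Trbc1 and Trbc2 in monocytes and macrophages. It came to 26.3% ± 0.6 of counts in NTC and 21.4% ± 1.8 in Il1a-targeted tumors in monocytes and macrophages (SD), 36.1% ± 2.5 and 24.8% ± 0.3 in T cells, 32.2% ± 0.9 and 24.7% ± 3.3 in NK cells, and 35.3% ± 4.1 and 28.6% ± 0.8 in DCs. A gene expected at 50% or more from it in either group is called mostly free RNA. The estimate includes any true expression of these genes and any remaining doublets, so it is an upper estimate for RNA of the sorted cells. RNA of cells outside the sort is little held in a profile summed over sorted cells and can be underestimated. A gene under 50% is therefore not shown to be without free RNA.

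Tests, thresholds, gene lists, markers and the rule for named genes were fixed before the data were examined, but the doublet rate was not. The rule took, in monocytes and macrophages, the 8 called genes per direction of largest change whose tumors do not overlap between groups and whose mean is at least 50 CPM in the higher group, and 4 per direction elsewhere. It left out ribosomal protein and mitochondrial genes, Gm and Rik models and antigen receptor segments. It added the 3 members of highest CPM of each list that passed, and Il1a, Il1b, Il1rn, Il1r1, Il1r2, Arg1, Nos2 and Cd274, with Ifng, Gzmb, Pdcd1 and Foxp3 in T and NK cells. Members given with a list's count outside this rule were chosen after their values were seen. Not every gene the rule takes is reported here.

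Alternatives were DESeq2, RLE factors, no filter on low counts, each tumor left out, Leiden resolutions 0.5 and 2, doublets kept, at least 500 genes with at most 10% mitochondrial counts, equal cells per tumor, other denominators of shares, camera with an estimated correlation, and fry. The plan had been to remove the doublets that Scrublet predicts with its automatic threshold. That threshold marked 1261 cells (16.9%) in Il1a-targeted tumor 2 and 0 in the 4 others. The proportional rate therefore replaced it after the data were seen, and the automatic threshold was kept as an alternative. Others were chosen after seeing the data: free RNA subtracted, genes of free RNA left out, CD8 T cells alone, and mixed cells counted as regulatory T cells. On simulated data with 100 genes shifted by a log2 change of 1 and 100 by 2, the test called 99% and 100% of them in monocytes and macrophages with 19 false calls among 19044 genes. In T cells it called 100% of both with 24 false calls among 12560 genes. Shifted genes were taken above a minimum mean level. Counts were drawn from the dispersions fitted to the data, with no difference between libraries. These rates therefore check the code and do not give the power or error rate in the real tumors. Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.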

Results

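Immune cells were compared between mouse mammary tumors grown from cancer cells whose Il1a gene was targeted and tumors grown from cells with a non-targeting guide (NTC). Il1a encodes IL-1α, a cytokine that dying cells release as an alarm signal. The series title ties its release during necrotic-like cell death to suppression of immunity by myeloid cells. The cancer cells were a PyMT mammary line expressing Cas9, implanted into mammary fat of C57BL/6 females at the age of 8 weeks, and the untreated tumors were taken at day 14. Live CD45+ cells, the immune cells, were sorted and sequenced as single cells from NTC tumors 1, 2 and 3 and Il1a-targeted tumors 2 and 3. In this order, 8017, 7832, 8557, 7017 and 16425 cells were retained, with medians of 18441, 19812, 19067, 15372 and 22800 UMIs per cell. The labels give 1 gene expression library per group, so library and group cannot be told apart, and each p measures only the spread between tumors within a library. The 5 tumors allow 10 splits, so an exact permutation p cannot go below 0.1.

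Il1a itself was measured here in host immune cells, not in the edited cancer cells. Over all sorted cells, Il1a (ENSMUSG00000027399, mm10 chromosome 2, 129299610 to 129309972, minus strand) stood at 72.9 ± 17.2 CPM in NTC tumors (SD, n = 3) and 51.4 ± 3.15 in Il1a-targeted tumors (n = 2, edgeR adjusted p = 0.228). In monocytes and macrophages it was 79.4 ± 15.9 and 61.6 ± 12.3 CPM (adjusted p = 0.25). It fell in DCs, from 30.6 ± 2.96 to 15.3 ± 2.30 CPM (log2 -1.04, adjusted p = 0.0267), and in T cells, from 22.5 ± 1.79 to 11.2 ± 0.786 CPM (log2 -0.98, adjusted p = 0.00275), at levels of which free RNA would give 85.3% and 92.3% in DCs and 116% and 113% in T cells. The call in DCs did not pass when any 1 of the 5 tumors was left out, at log2 changes of -1.17 to -0.87. An unnamed cluster led by Hmga2, Tnc and the epithelial keratin Krt18 held 104, 97 and 96 cells of the NTC tumors and 61 and 108 of the Il1a-targeted ones. There Il1a was 18.8 (Poisson 95% interval 14.8 to 23.4), 26.4 (21.8 to 31.6) and 25.6 (21.3 to 30.6) CPM in the NTC tumors. It was 9.06 (6.31 to 12.6) and 9.46 (7.40 to 11.9) CPM in the Il1a-targeted tumors, while Krt18 was 626, 646 and 556 against 704 and 594 CPM. Ptprc, which encodes CD45, was 168, 232 and 238 against 136 and 178 CPM in these cells. Macrophages of the same tumors held 61.7, 85.7 and 90.0 against 69.9 and 53.4 CPM of Il1a. The sort was set to remove cancer cells, free RNA of macrophages reaches every droplet, and an edited gene can still give 3' tags. These levels therefore do not check the labels.

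CD8 T cells, the cytotoxic lymphocytes, made up 51.5% ± 5.02 of T cells in NTC tumors (SD, n = 3) and 74.1% ± 5.22 in Il1a-targeted tumors (n = 2). Every Il1a-targeted tumor (77.8% and 70.4%) lay above every NTC tumor (54.4%, 45.8% and 54.5%), which gave the smallest p the exact permutation test allows (two-sided p = 0.1, adjusted p = 0.2). CD4 T cells, the helper subset, were 10.1% ± 2.69 and 5.27% ± 0.910 of T cells (permutation p = 0.2). Regulatory T cells, which restrain immune responses, were 16.2% ± 5.55 and 6.97% ± 4.49 of T cells (permutation p = 0.2), with 16%, 21.9% and 10.8% in the NTC tumors and 3.79% and 10.1% in the Il1a-targeted ones. With cells that also held macrophage RNA counted as regulatory T cells, the shares were 28.6% ± 11.5 and 10.2% ± 4.03. T or NK cells left without a subset name were 21.9% ± 0.823 and 13.2% ± 0.168 of T cells (permutation p = 0.1). By edgeR on cell counts, the CD8 subset was higher by 0.52 on the log2 scale (adjusted p = 0.020). By the same test, the CD4 subset was lower with a log2 ratio of -0.95 (adjusted p = 0.035), and regulatory T cells had a ratio of -1.21 (adjusted p = 0.10). That fit held only these subsets, whose counts make up nearly all T cells. A larger share of 1 subset lowers the others, so its p-values are not independent of each other.

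T cells were 6.46% ± 2.21 of retained cells in NTC tumors and 15.8% ± 11.6 in Il1a-targeted tumors, a difference of 9.37 percentage points (exact permutation p = 0.3, adjusted p = 0.875). That difference rested on Il1a-targeted tumor 2, with 24.0% T cells, and was 1.16 points without it. Monocytes and macrophages were the largest class, with 79.1% ± 5.10 and 69.5% ± 22.1 of cells (permutation p = 0.7), at 53.9% and 85.2% in Il1a-targeted tumors 2 and 3. NK cells were 1.33% ± 0.703 and 2.06% ± 1.66 (permutation p = 0.7), and B cells 0.472% ± 0.196 and 1.35% ± 1.32 (permutation p = 0.2). Neutrophils were 1.38% ± 0.574 and 0.746% ± 0.598 (permutation p = 0.4), and conventional and mature dendritic cells (DCs) 2.42% ± 1.01 and 1.69% ± 0.467 (permutation p = 0.5). No class passed a threshold of 0.05, which these splits cannot reach.

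**Figure D1:**
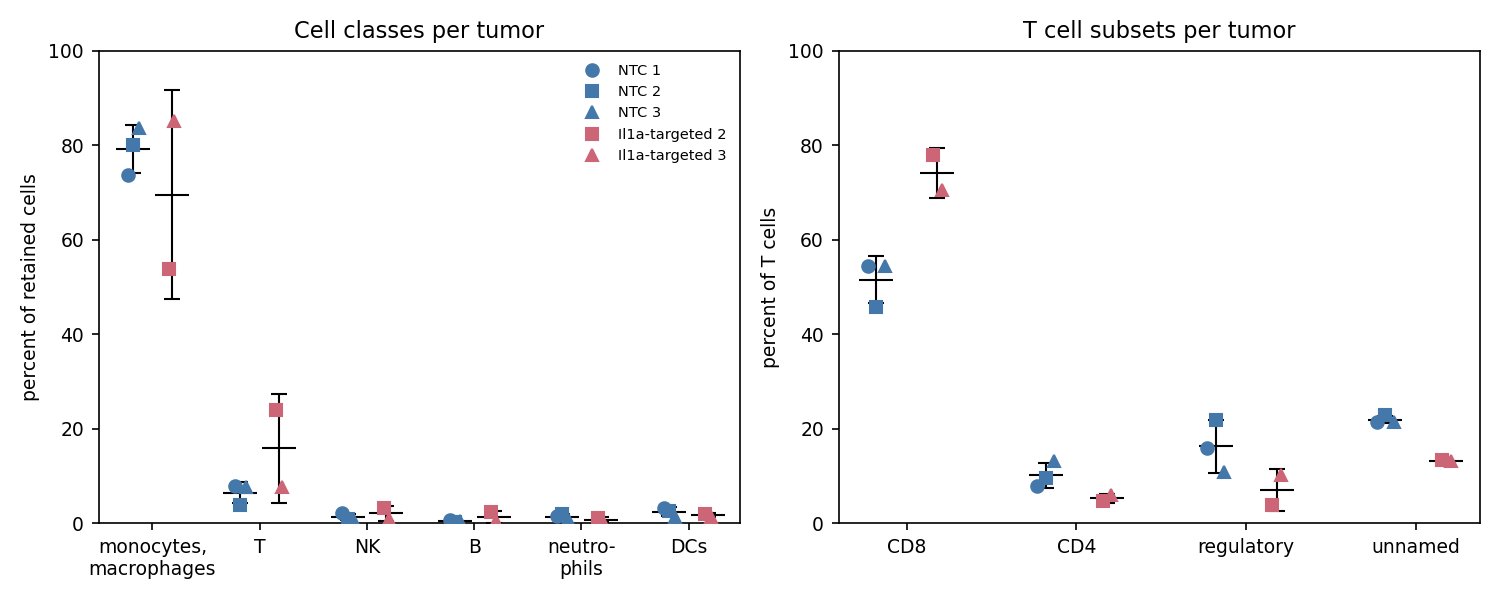
Cell classes as percent of retained cells (left) and T cell subsets as percent of T cells (right), with 1 point per tumor and bars at the mean ± SD of each group. The CD8 share of T cells lies between 45.8% and 54.5% in the 3 NTC tumors and at 70.4% and 77.8% in the 2 Il1a-targeted tumors.

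In monocytes and macrophages, 11 of 22 type I interferon response genes, 12 of 20 interferon gamma response genes and 8 of 15 MHC class I genes were higher in Il1a-targeted tumors, and the matrix and cytokine gene Spp1, the platelet-factor chemokine Pf4 and the metallothionein Mt2 were lower. These counts of members do not hold with predicted doublets kept, where 10 genes of the whole class were called higher. They also fall without either Il1a-targeted tumor, while the lists still passed camera with the preset correlation. Iigp1, a GTPase induced by interferon gamma (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634, plus strand), rose from 90.3 ± 35.7 CPM (SD, n = 3) to 285 ± 56.0 (n = 2), a log2 fold change of 1.66 ± 0.32 (SE, adjusted p = 0.0447). The eosinophil-attracting chemokine Ccl24 (ENSMUSG00000004814, chromosome 5, 135569937 to 135573049, minus strand) had the largest rise of the named genes, from 30.4 ± 13.8 to 152 ± 15.8 CPM (log2 2.32 ± 0.35, adjusted p = 0.0351). Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050, plus strand) fell from 2746 ± 1016 to 791 ± 31.9 CPM (log2 -1.80 ± 0.32, adjusted p = 0.0416).

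Among 22 measured type I interferon response genes, 11 were higher, 0 lower and 11 not called, with 22 higher adjusted over the list alone (median log2 0.76). Examples were Ifi44 (log2 1.47), Irf7 (0.94) and Oas3 (0.87). The list passed camera (adjusted p = 3.55e-11, and adjusted p = 0.456 with an estimated correlation). Of 20 interferon gamma response genes, 12 were higher and 0 lower, 19 higher adjusted over the list alone (median 1.18, camera adjusted p = 4.13e-10, and adjusted p = 0.456 with an estimated correlation). Gbp2, a guanylate-binding protein of cell-autonomous defense, rose from 154 ± 47.3 to 408 ± 113 CPM, and Cxcl10, which attracts T cells, from 171 ± 52.1 to 394 ± 72.1 CPM. Cxcl9, of like function, was at 323 and 1073 CPM without passing (adjusted p = 0.0739). Of 15 MHC class I genes, 8 were higher and 0 lower, 15 higher adjusted over the list alone (median 0.63, camera adjusted p = 9.74e-09, and adjusted p = 0.456 with an estimated correlation). H2-D1, which presents peptides to CD8 T cells, rose from 755 ± 69.3 to 1063 ± 23.1 CPM, and the peptide transporter gene Tap1 by 0.78 on the log2 scale. Of 10 MHC class II genes, 0 were called by edgeR over all genes, where 5281 genes of the class stood at an unadjusted p under 0.05 and DESeq2 called 2628, and 8 were higher adjusted over the list alone. As a list they rose (median 0.88, camera adjusted p = 0.0018, and adjusted p = 0.515 with an estimated correlation), with H2-Ab1 at 1340 ± 543 and 2835 ± 216 CPM. Macrophage cluster composition moved with these lists. A cluster led by Cxcl9, Cadm1 and Cd72 held 1.63% of the class in NTC and 16.6% in Il1a-targeted tumors, and a cluster led by Ccl8 and Vcam1 5.42% and 20.6%.

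Glycolysis and hypoxia genes fell as a list in monocytes and macrophages. Of 20 measured, 3 were lower and 0 higher, and 13 were lower adjusted over the list alone (median log2 -0.38, camera adjusted p = 1.18e-05, and adjusted p = 0.467 with an estimated correlation). The called members were the enolase Eno1 (log2 -0.75), the hypoxia-induced hydroxylase Egln3 (-1.09) and Ndrg1 (-0.75). The cluster led by Spp1, Cxcl2 and Arg1 held 9.59% of the class in NTC and 0.67% in Il1a-targeted tumors, and that led by F13a1, Nrg1 and Fn1 22.9% and 1.48%. Monocyte markers summed to 6223 ± 1704 and 3184 ± 32.2 CPM (exact permutation p = 0.2), and macrophage markers to 21570 ± 1592 and 20445 ± 2044 CPM (permutation p = 0.6). The monocyte markers include F13a1 and Fn1, which lead the macrophage cluster just given, so their sum does not show fewer monocytes. The cluster led by the monocyte markers Plac8 and Chil3 held 3.31% of the class in NTC and 4.24% in Il1a-targeted tumors. The glycolysis and hypoxia list also fell in the 5 other classes, with medians of -0.56 in DCs, -0.54 in neutrophils, -0.45 in T cells, -0.48 in NK cells and -0.66 in B cells (camera adjusted p = 1.99e-11, 1.01e-07, 2.38e-09, 1.82e-10 and 4.94e-09, and adjusted p = 0.330 for each with an estimated correlation). Mostly free RNA were 9 of 19 members in DCs, 17 of 19 in neutrophils, 14 of 20 in T cells, 15 of 19 in NK cells and 18 of 18 in B cells. With such genes left out, the list passed in DCs (adjusted p = 2.68e-07) and T cells (0.00274), and the other classes kept too few members for a test.

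The suppressive myeloid gene list did not pass in monocytes and macrophages, and fell in DCs. In DCs 7 of 24 members were lower and 0 higher (median log2 -0.49, camera adjusted p = 4.99e-07, and adjusted p = 0.330 with an estimated correlation), but 18 members were mostly free RNA, and the list did not pass with these left out (adjusted p = 0.137) or with free RNA subtracted (0.32). In monocytes and macrophages, 3 of 26 measured genes were lower (Spp1, S100a8 and S100a9), 0 higher and 23 not called (median log2 -0.09, camera adjusted p = 0.254). At least 66.0% of the S100a8 and S100a9 level in each group was expected from free RNA of other cells. Arg1, whose enzyme depletes arginine, was at 2183 ± 592 and 1161 ± 75 CPM (adjusted p = 0.0704). The checkpoint ligand Cd274 was at 151 ± 39.3 and 292 ± 73.0 CPM (adjusted p = 0.0653), and Nos2 had a log2 change of 0.43 ± 0.39 (adjusted p = 0.508). Among 21 measured genes of the IL-1 family and receptors, 4 were higher (Il18bp, Myd88, Casp1 and Casp4), 1 was lower (Il1rap, the shared receptor chain) and 16 were not called (camera adjusted p = 0.174). Il1b, the sister cytokine, was at 1724 and 1712 CPM (log2 -0.01 ± 0.09, adjusted p = 0.955). Of 27 NF-kB and inflammatory genes, 1 was higher (Nfkbiz) and 2 were lower, the neutrophil attractants Cxcl1 (log2 -1.30) and Cxcl2 (-0.85), with a median log2 change of 0.06, a mean of -0.07 and a camera adjusted p of 0.575. Of 21 chemokines, 2 were higher (Ccl24 and Cxcl10) and 6 lower, among them Ccl6, Ccl9 and Pf4 (camera adjusted p = 0.151). Adjusted over the list alone, 2 suppressive genes were higher and 5 lower, and 5 and 1 of the IL-1 family. For NF-kB genes these counts were 5 and 5, and for chemokines 6 and 11. Camera tests for a shift in 1 direction, so not passing it does not show that members of these lists were unchanged. The individual members given here for lists that did not pass were chosen after their values were seen, apart from Spp1, Pf4, Ccl24, Cxcl10, Arg1, Nos2, Cd274 and Il1b.

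In all, 816 of 19044 genes tested in monocytes and macrophages passed by edgeR, 423 higher and 393 lower in Il1a-targeted tumors. The count was 3171, 356 and 50 without NTC tumors 1, 2 and 3, 8 without either Il1a-targeted tumor, 2628 by DESeq2 (789 of them shared), and 26 with predicted doublets kept. Of the 816, 162 (19.9%, against 7.3% of genes tested) were expected mostly from free RNA of other cells, such as the cathepsin gene Ctsk (51.9 and 21.3 CPM), and 193 passed with all such genes left out of the fit. The 654 other called genes had a median absolute log2 change of 0.71 in both fits, with a median SE of 0.121 before and 0.12 after. In the fit without free RNA genes Ccl24 and Mt2 passed, while Iigp1 in monocytes and macrophages (log2 1.66, adjusted p = 0.0552) did not, nor did Spp1, Pf4, Gbp2, H2-D1 or Cxcl10. With predicted doublets kept, none of these 8 genes passed.

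**Figure D2:**
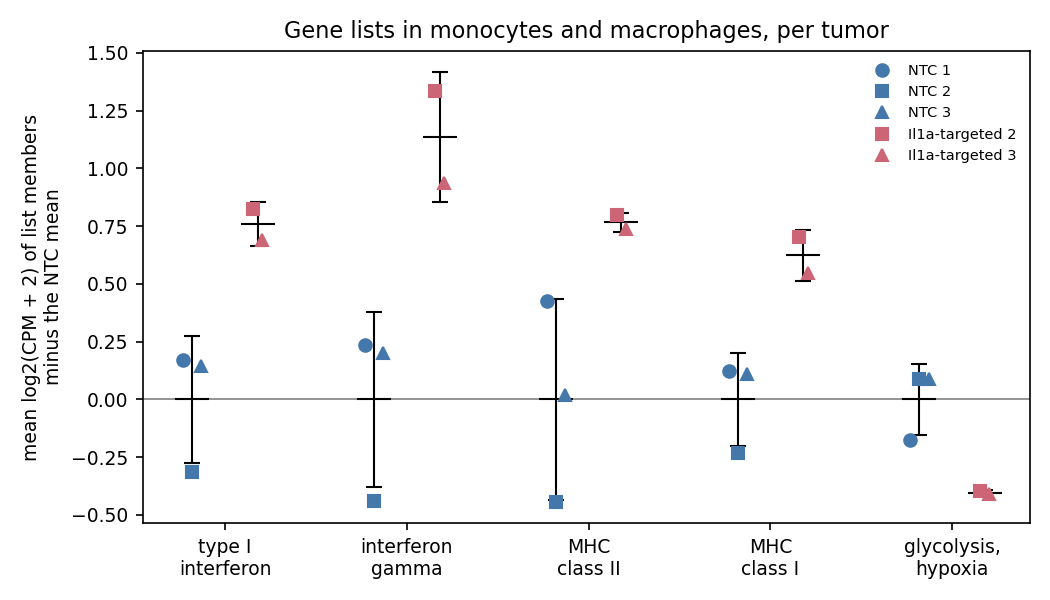
Mean log2 CPM of the measured members of 5 gene lists in monocytes and macrophages, minus the mean of the NTC tumors, with 1 point per tumor and bars at the mean ± SD of each group. In the interferon gamma list the NTC tumors lie between 5.28 and 5.96 log2 CPM before this subtraction, and both Il1a-targeted tumors at 6.66 or above.

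In conventional and mature DCs, 10 of 19 glycolysis and hypoxia genes and 3 of 10 MHC class II genes were lower in Il1a-targeted tumors, and 2 of 22 type I interferon and 3 of 20 interferon gamma genes were higher. Gapdh fell from 1328 ± 33.3 to 873 ± 85.0 CPM (log2 -0.60 ± 0.08, adjusted p = 0.0191), and Il1b from 3142 ± 124 to 2329 ± 180 CPM (log2 -0.43 ± 0.07, adjusted p = 0.0258). Cadm1 (ENSMUSG00000032076, chromosome 9, 47530173 to 47857637, plus strand), an adhesion molecule of type 1 conventional DCs, rose from 71.7 ± 20.3 to 227 ± 67.9 CPM (log2 1.63 ± 0.23, adjusted p = 0.0238). Cadm1 also led a macrophage cluster that held 1.63% of monocytes and macrophages in NTC and 16.6% in Il1a-targeted tumors. Its rise in DCs therefore does not by itself show a change in type 1 DCs. Pgf, a growth factor of the VEGF family, fell from 76.3 to 23.4 CPM (log2 -1.66 ± 0.26, adjusted p = 0.0261). Of 19 glycolysis and hypoxia genes, 10 were lower and 0 higher, 17 lower adjusted over the list alone (median log2 -0.56, camera adjusted p = 1.99e-11, and adjusted p = 0.330 with an estimated correlation). Examples were Eno1 (log2 -0.81), Tpi1 (-0.68) and Ldha (-0.40), and 9 members were expected mostly from free RNA in at least 1 group. Of 10 MHC class II genes, 3 were lower (Cd74, H2-DMb2 and H2-Oa), 0 higher, and 6 lower adjusted over the list alone (median -0.28, camera adjusted p = 0.00564, and adjusted p = 0.507 with an estimated correlation). The list did not pass without Il1a-targeted tumor 2 or with the automatic doublet threshold, which removed cells of that tumor alone. Cd74, the invariant chain, fell from 13370 ± 374 to 10930 ± 1001 CPM. Of 22 type I interferon genes, 2 were higher (Ifit3 and Oasl1), 13 adjusted over the list alone (median 0.57, camera adjusted p = 4.24e-08, and adjusted p = 0.410 with an estimated correlation). Of 20 interferon gamma genes, 3 were higher (Gbp5, Irf1 and Irgm1), 11 adjusted over the list alone (median 0.65, camera adjusted p = 8.32e-07, and adjusted p = 0.467 with an estimated correlation).

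Markers of type 1 conventional and of mature DCs stood apart between the groups in these cells, and those of type 2 conventional DCs overlapped. Type 1 conventional DC markers summed to 1372 ± 97.9 CPM in NTC and 2263 ± 122 in Il1a-targeted tumors, and mature DC markers to 1236 ± 64.5 and 1523 ± 147 CPM (exact permutation p = 0.1 for each). Type 2 markers were at 1112 ± 160 and 891.7 ± 150 CPM (permutation p = 0.3). The type 1 markers were also higher outside DCs, at 521 ± 52.5 and 822 ± 10.3 CPM in monocytes and macrophages and 587 ± 16.9 and 808 ± 10.3 CPM in B cells (permutation p = 0.1 for each). They include Cadm1, a leading gene of a macrophage cluster, so their sum does not show more type 1 DCs. The mature DC cluster held 21.3%, 21.4% and 19.6% of DCs in the NTC tumors and 31.7% and 19.2% in the Il1a-targeted ones. Neutrophil markers stood at 2597 ± 380 and 1686 ± 690 CPM in the same cells, and T cell markers at 80.7 and 231 CPM (permutation p = 0.1 for each). The neutrophil markers include Il1r2, a leading gene of the main DC cluster, so their sum is not a measure of neutrophil RNA alone. Of 11205 genes tested in DCs, 253 passed by edgeR, 83 higher and 170 lower, and 90 of these (35.6%, against 23.7% of genes tested) were mostly free RNA. The count was 160, 11 and 29 without NTC tumors 1, 2 and 3, and 15 and 71 without Il1a-targeted tumors 2 and 3. It was 8 with the automatic doublet threshold and 0 with free RNA subtracted, where 1232 genes stood at an unadjusted p under 0.05. With genes of free RNA left out it was 179, of which 160 were among the 253.

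In T cells, 4 of 17 cytotoxic effector genes (Gzmk, Fasl, Tbx21 and Klrd1) and 3 of 15 checkpoint genes (Pdcd1, Lag3 and Havcr2) were higher in Il1a-targeted tumors. T cell markers summed to 4223 ± 307 CPM in NTC and 5373 ± 111 in Il1a-targeted tumors (exact permutation p = 0.1), and free RNA was estimated at 36.1% and 24.8% of the counts of these cells. Klrc1, the inhibitory receptor chain NKG2A, rose from 185 ± 8.62 to 319 ± 28.6 CPM (log2 0.78 ± 0.08, adjusted p = 0.000731) and was singled out after its values were seen. Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553, minus strand), the checkpoint receptor PD-1, rose from 188 ± 8.97 to 241 ± 6.53 CPM (log2 0.36 ± 0.07, adjusted p = 0.0173). In the cytotoxic effector list 1 gene was lower (Srgn) and 12 were not called, with 7 higher and 2 lower adjusted over the list alone. The list passed camera (median log2 0.40, adjusted p = 0.0116, and adjusted p = 0.333 with an estimated correlation). It also passed with genes of free RNA left out (16 members kept, adjusted p = 0.0172), and did not with free RNA subtracted (adjusted p = 0.214). Fasl, a ligand that triggers cell death, rose from 72.1 ± 3.04 to 106 ± 3.44 CPM. Ifng was at 236 ± 65.2 and 365 ± 72.4 CPM (adjusted p = 0.101), Gzmb had a log2 change of 0.52 (adjusted p = 0.274), and Foxp3, the regulatory T cell factor, one of -0.97 (adjusted p = 0.205). With each tumor left out, these ranged from 0.04 to 0.88 for Gzmb and from -1.97 to -0.33 for Foxp3, and Gzmb, Foxp3 and Ifng (log2 0.80) passed without Il1a-targeted tumor 3, as did Ifng without NTC tumor 3 (log2 0.85). In the checkpoint and exhaustion list 0 genes were lower by edgeR and 12 not called, where 2604 genes of the class stood at an unadjusted p under 0.05 and DESeq2 called 697, with 6 higher and 1 lower adjusted over the list alone. That list passed camera (median 0.18, adjusted p = 0.0472, and adjusted p = 0.456 with an estimated correlation), and did not with genes of free RNA left out (adjusted p = 0.183), with free RNA subtracted (0.958) or without NTC tumor 1 or 3 or Il1a-targeted tumor 3. Its mean was 7.28, 7.29 and 7.26 log2 CPM in the NTC tumors and 7.24 and 7.48 in Il1a-targeted tumors 2 and 3, so tumor 2 lay below every NTC tumor. Of 15 MHC class I genes, 2 were higher (Nlrc5 and H2-T23), 3 adjusted over the list alone (median 0.17, camera adjusted p = 6.64e-05, and adjusted p = 0.330 with an estimated correlation). This list passed with genes of free RNA left out (all 15 members kept, adjusted p = 0.000363), and did not with free RNA subtracted (median 0.02, adjusted p = 0.677). CD8 T cells made up 51.5% and 74.1% of the T cells behind these values, so a rise can come from this share. In CD8 T cells alone, 398 of 11454 genes passed by edgeR. With genes of free RNA left out there, 0 of 9146 passed, Klrc1 and Pdcd1 included, while 1062 stood at an unadjusted p under 0.05. Pdcd1 did not pass without NTC tumor 1 or 3 or either Il1a-targeted tumor (log2 0.34 to 0.39), with genes of free RNA left out (0.32) or with free RNA subtracted (0.14).

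Many more genes passed in T cells at levels that free RNA of macrophages would give. Of 12560 genes tested, 749 passed by edgeR, 214 higher and 535 lower, and 505 of these were expected at 50% or more from free RNA in at least 1 group, against 22.7% of genes tested. They included Spp1 (945 and 210 CPM, 98.4% and 89.9% expected from free RNA) and Arg1 (657 and 222 CPM, 110% and 115%). Macrophage markers in T cells summed to 6784 ± 447 and 4508 ± 41.8 CPM (exact permutation p = 0.1). Lists of macrophage genes, such as suppressive myeloid genes (21 of 25 members mostly free RNA) and lipid-associated macrophage genes (16 of 16), fell in T cells (camera adjusted p = 4.48e-14 and 1.24e-10, and adjusted p = 0.330 for each with an estimated correlation). With such genes left out, 3 passed, Klrc1 and Rbms3 higher and H1f0 lower. The 244 other called genes kept a median absolute log2 change of 0.44 (0.45 before) with a median SE of 0.093 in both fits. The count of 749 became 280 without Il1a-targeted tumor 2, and 347 and 486 without NTC tumors 1 and 2.

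**Figure D3:**
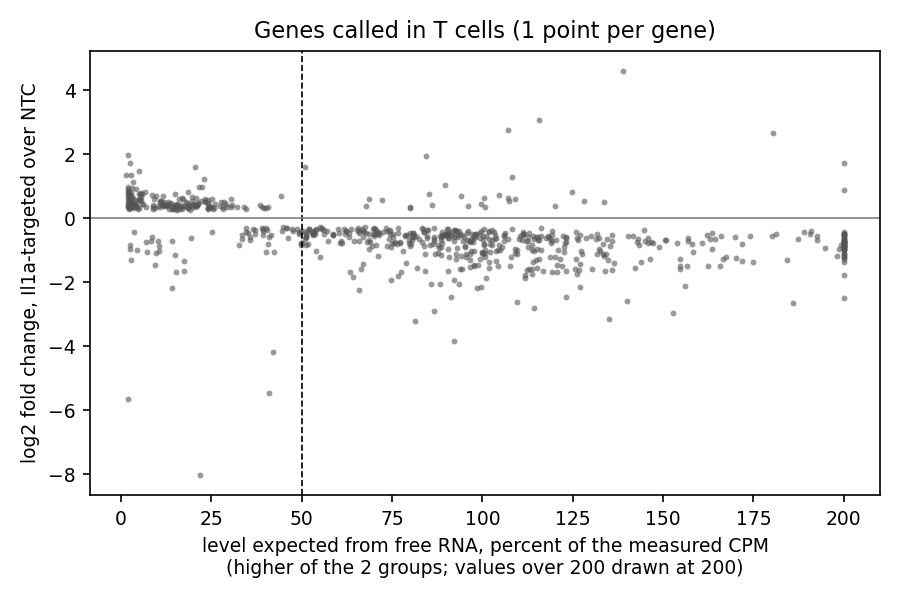
Log2 fold change of the 749 genes called in T cells against the level expected from free RNA, as percent of the measured CPM in the group where it is higher, with 1 point per gene and values over 200 drawn at 200. The dashed line stands at 50%, and 505 genes lie on it or to its right.

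In NK cells, 3 of 16 cytotoxic genes (Gzmb, Prf1 and Ifng) were higher in Il1a-targeted tumors. Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260, minus strand), the granule protease granzyme B, rose from 476 ± 57.5 CPM (SD, n = 3) to 1011 ± 323 (n = 2), a log2 change of 1.09 ± 0.16 (SE, adjusted p = 0.00304). Ifng, the gene of interferon gamma, rose from 42.7 ± 7.67 to 77.3 ± 3.19 CPM (log2 0.84 ± 0.18, adjusted p = 0.0419), and Prf1, the pore-forming perforin, by 0.71 on the log2 scale. The cytotoxic list rose, with 6 of 16 members higher adjusted over the list alone (median log2 0.37, camera adjusted p = 0.000174, and adjusted p = 0.330 with an estimated correlation). Proliferation genes fell as a list, with 0 of 26 called by edgeR, where 922 genes of the class stood at an unadjusted p under 0.05 and DESeq2 called 58 (median -0.48, camera adjusted p = 0.00158, and adjusted p = 0.569 with an estimated correlation). The proliferation list turned in direction without Il1a-targeted tumor 2 and did not pass without NTC tumor 2, and its mean was 5.18, 5.95 and 5.30 log2 CPM in the NTC tumors and 4.66 and 5.49 in the Il1a-targeted ones. NK markers summed to 4114 ± 747 and 6340 ± 2283 CPM and macrophage markers to 5977 ± 294 and 4397 ± 430 CPM (exact permutation p = 0.2 and 0.1). Of 9998 genes tested, 86 passed by edgeR, 20 higher and 66 lower, and 73 of these (84.9%, against 18.8% of genes tested) were expected mostly from free RNA. Without such genes 1 passed, and the count of 86 became 33 and 47 without NTC tumors 1 and 3, and 18 and 35 without Il1a-targeted tumors 2 and 3. With genes of free RNA left out, neither Gzmb in NK cells (adjusted p = 0.0695) nor Ifng in NK cells (adjusted p = 0.385) passed. The 13 other called genes had a median absolute log2 change of 0.72 in that fit and 0.75 before. The cytotoxic list passed camera with such genes left out (14 members kept, adjusted p = 7.19e-05). Gzmb did not pass without Il1a-targeted tumor 2 (log2 0.71), and Ifng did not pass when any 1 of the 5 tumors was left out (log2 0.72 to 0.90).

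Neutrophils and B cells were few and held much free RNA, estimated at 63.5% ± 2.1 and 65.4% ± 5.3 of counts in neutrophils and 74.4% ± 16.2 and 53.0% ± 9.0 in B cells. In neutrophils 16 of 6691 genes passed by edgeR, 7 higher and 9 lower, and 13 of them (81.2%) were mostly free RNA, no more than the 85.2% of genes tested. Ifit1, an interferon-induced RNA sensor, rose from 51.1 ± 32.1 to 237 ± 23.3 CPM (log2 2.28 ± 0.39, adjusted p = 0.0480), with 32.2% and 11.0% of its level expected from free RNA. It did not pass with genes of free RNA left out (log2 2.08, adjusted p = 0.339) or without NTC tumor 1 or 2 or either Il1a-targeted tumor. Of 21 type I interferon genes in neutrophils, 1 was higher and 0 lower, 12 higher adjusted over the list alone (median log2 0.84, camera adjusted p = 2.59e-11, adjusted p = 0.330 with an estimated correlation, and 4.51e-06 with free RNA genes left out). Arg1 fell with a log2 change of -1.14, at levels of which free RNA would give 110% and 127%. In B cells 2 of 7191 genes passed, 1 in each direction and both mostly free RNA, as were 85.2% of genes tested, while 632 stood at an unadjusted p under 0.05 and DESeq2 called 22. The neutrophil count was 1 without NTC tumor 1 or 2, 35 without NTC tumor 3, and 4 and 3 without Il1a-targeted tumors 2 and 3, and that of B cells was 0 without NTC tumor 2 or Il1a-targeted tumor 3 and 11 without NTC tumor 3.

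Over all sorted cells, 0 of 19969 genes passed by edgeR, while 4390 stood at an unadjusted p under 0.05 and DESeq2 called 2095. Arg1 had a log2 change of -1.02 (adjusted p = 0.156), Cd274 of 0.78 (adjusted p = 0.153) and Il1b of -0.13 (adjusted p = 0.387). Without Il1a-targeted tumor 3, whose macrophage share was the highest, 838 genes passed, and 1 without Il1a-targeted tumor 2.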

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

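The tests of macrophage clusters and of library number were chosen after the results were seen.

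MHC class II genes moved apart between cell classes, with every tumor of 1 class on the opposite side of the other. On the mean of the members in log2 CPM, the change in monocytes and macrophages minus that in DCs was 1.02 (exact permutation p = 0.2). The change in neutrophils minus that in DCs was 1.25 (permutation p = 0.1), with 7 of 7 members in neutrophils mostly free RNA. The change in DCs minus that in T cells was -0.54 (permutation p = 0.1), with 9 of 10 members in T cells mostly free RNA. The change in DCs minus that in B cells was -0.75 (permutation p = 0.1), with 6 of 10 members in B cells mostly free RNA. These p-values cannot go below 0.1, so none of the 4 differences is shown by its test.

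The macrophage side of this pattern, with the interferon, MHC class I and glycolysis lists, was weighed against technical explanations. Subtracting free RNA left at least 102.5% of each list's median change, but this decides nothing, since 62.7% to 89.2% of a tumor's counts came from this class and the estimate is built from them, so free RNA could still play a part. Within each of the 11 macrophage clusters used, the interferon gamma and MHC lists were higher in Il1a-targeted tumors. Their median over clusters was at least 68.4% of the change over the class (interval from 32.4%). A change was thus measured within clusters. Free RNA, estimated at 26.3% of counts in NTC and 21.4% in Il1a-targeted tumors in this class, carries a shifted mix into every cluster. The change within clusters therefore does not exclude the mix as its source. The interval treats clusters as independent, though all hold cells of the same 5 tumors, so it is too narrow to rely on. The cluster led by Cxcl9, Cadm1 and Cd72 was left out for few cells. Its interferon gamma change was 0.275, and that of the cluster led by Ccl8 and Vcam1 0.295, against 1.12 over the class. For the type I interferon list the median over clusters was 55.8% (interval 24.2% to 97.8%), which leaves a change within clusters, though the mix could carry much of it. For the glycolysis list it was 55.2% (-3.2% to 102.4%), where the mix could carry all in this class. The glycolysis list had medians of -0.66 to -0.45 in the 5 other classes. There 9 to 18 members were mostly free RNA, which can come from macrophages, so these medians are not apart from that mix. Without such genes the list still passed camera in DCs (adjusted p = 2.68e-07) and T cells (0.00274). With 1 library per group, a difference between libraries cannot be told apart from the loss of tumor cell Il1a, which may also raise these genes.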

How the results depend on the processing

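The proportional doublet rate of the main fit, both treatments of free RNA, CD8 T cells alone and mixed cells counted as regulatory T cells were chosen after the data were seen. The automatic doublet threshold was the first plan. Of 1957 values of named genes under an alternative, 1429 kept their direction and their side of the threshold, 458 no longer passed, 25 newly passed and 45 turned in direction. Of 876 values of gene lists that had passed, 643 still passed in their direction, 219 no longer passed and 14 turned. RLE factors in edgeR left the counts of called genes in all classes within 1.5 times, and all 131 named genes on their side of the threshold. The 5 macrophage lists of interferon, MHC and glycolysis genes passed camera with a preset correlation in their direction without each tumor and under each cell filter, resolution, doublet setting and treatment of free RNA. They did not pass with an estimated correlation or by fry. With 1 Il1a-targeted tumor left out, the other stands alone and is assumed to vary like the NTC tumors. B cells and neutrophils had as few as 27 and 53 cells in a tumor. With genes of free RNA left out in T cells, 1359 of 9715 genes stood at an unadjusted p under 0.05, against 2604 of 12560 before, and a lower share of small p-values raises the adjusted p at a given p. Doublets were called per tumor, at a rate meant for doublets within a tumor, although the tumors of a group shared a library. Doublets across tumors that the split by hashtag may have left are not in that rate. The count in monocytes and macrophages moved with doublet settings. The cause was not tested for the values below unless stated.

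By DESeq2 the number of genes passing was 2628 in monocytes and macrophages, 36 in neutrophils, 22 in B cells and 2095 in all sorted cells. With genes of free RNA left out, DESeq2 called 2298 in monocytes and macrophages, 281 in DCs and 158 in T cells. Without a filter on low counts it was 2096 in monocytes and macrophages, 193 in neutrophils, 1243 in DCs, 1555 in T cells, 216 in NK cells, 130 in B cells and 18 in all sorted cells. With predicted doublets kept it was 26 in monocytes and macrophages and 7 in neutrophils, and with the stricter cell filter 8 in neutrophils. The automatic doublet threshold marked 1261 cells (16.9%) in Il1a-targeted tumor 2 and 0 in the 4 others, so it filters 1 tumor of 1 group and keeps the doublets of the rest. It gave 151 in monocytes and macrophages, 3 in neutrophils, 8 in DCs and 0 in B cells. Leiden resolution 0.5 gave 153 in DCs, 486 in T cells and 211 in NK cells. Equal cells per tumor gave 1 in neutrophils, 58 in DCs, 367 in T cells, 29 in NK cells and 12 in B cells. With free RNA subtracted it was 4 in monocytes and macrophages, 23 in T cells, and 0 in neutrophils, DCs, NK cells and B cells. With genes of free RNA left out of edgeR it was 193 in monocytes and macrophages, 179 in DCs, 3 in T cells, 1 in NK cells and 0 in neutrophils and B cells. CD8 T cells alone gave 398, and 0 with genes of free RNA left out. Of the gene lists, 0 passed with an estimated correlation (lowest adjusted p = 0.33), 19 by fry, 32 with free RNA subtracted and 34 with its genes left out.

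Leaving out each tumor gave 8 to 3171 genes in monocytes and macrophages (0 to 2562 with genes of free RNA left out), 1 to 35 in neutrophils, 11 to 160 in DCs (0 to 136), 280 to 652 in T cells (0 to 94), 18 to 66 in NK cells (0 to 4), 0 to 11 in B cells (0 to 4) and 0 to 838 in all sorted cells. Differences in share ranged, in percentage points, from -25.2 to 6.03 for monocytes and macrophages, -0.057 to 0.176 for plasmacytoid DCs, -0.147 to 0.004 for mast cells or basophils, -0.451 to 1.90 for NK cells, -0.052 to 1.81 for B cells, -12.4 to -6.09 for regulatory T cells among T cells, and -4.43 to 4.37 for unnamed cells. Log2 changes over all sorted cells ranged from -0.15 to 0.0 for Il1rn and -0.46 to 0.62 for Nos2. In monocytes and macrophages they ranged from -0.12 to 0.22 for Il1rn, -0.07 to 0.05 for Il1b and -0.50 to 0.99 for Nos2. In neutrophils they ranged from -0.05 to 0.33 for Il1r2, -0.46 to 0.23 for Il1rn, -0.03 to 0.17 for Il1b and -1.16 to 0.87 for Nos2. In DCs the range was -0.14 to 0.82 for Il1r1 and -0.29 to 0.15 for Nos2, and in T cells -0.65 to 0.10 for Il1r1 and -0.04 to 0.09 for Cd274. In B cells it was -0.14 to 0.06 for Il1b, -2.32 to 1.62 for Nos2 and -0.21 to 0.48 for Cd274. The proliferation list in NK cells ranged from -0.85 to -0.06 and turned in test direction without Il1a-targeted tumor 2.

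In share of cells, monocytes and macrophages turned in direction among myeloid cells (0.691 points). In share of cells, NK cells turned among lymphoid cells (-5.75), as did unnamed cells at resolution 2 (0.113) and with the stricter filter (0.307). By edgeR on cell counts the log2 ratios of CD8 (0.52), CD4 (-0.95) and unnamed T cells (-0.73) passed. Log2 changes turned with the automatic doublet threshold for Il1b in macrophages (0.02), Il1rn in neutrophils (0.07), Nos2 in DCs (0.44) and Il1r2 in B cells (-0.22). With doublets kept they turned for Il1b in neutrophils (-0.04) and B cells (0.06), Nos2 in DCs (0.97) and Il1r2 in B cells (-0.02). With equal cells they turned for Il1rn (0.13) and Nos2 (0.23) in neutrophils, Il1r1 in DCs (-0.21) and T cells (0.15) and Cd274 in B cells (-0.32). Leiden resolution 2 turned Il1rn in DCs (0.14), resolution 0.5 Pdcd1 in NK cells (0.23), and no filter Il1b in B cells (0.03). With free RNA subtracted Il1b (0.71), C1qb (0.04) and Cd274 (-0.34) turned in T cells and Cd274 in B cells (-0.43). With its genes left out Il1r2 (-0.02) and Il1b (-0.11) turned in neutrophils and Cd274 in T cells (-0.03).

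Among lists that had passed, the mean or test direction turned for mitochondrial genes in neutrophils with doublets kept (0.04), NF-kB genes in DCs at resolution 2 (0.08) and in T cells with genes of free RNA left out (-0.06), and suppressive genes in NK cells with the latter (0.05). With free RNA subtracted it turned for lipid-associated macrophage genes in DCs (0.49), interferon gamma (-0.0) and chemokine genes (0.19) in T cells, and for the MHC class II list in NK cells (-0.69) and chemokine genes there (-0.15). In B cells that subtraction turned suppressive (0.50), interferon gamma (0.43), MHC class II (0.06) and naive and memory genes (-0.08).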

Other observations

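The tests of regulatory T cell shares and of free RNA among called genes were chosen after the results were seen.

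In monocytes and macrophages, proliferation genes rose slightly as a list, with 0 of 26 called by edgeR while 5281 genes of the class stood at an unadjusted p under 0.05 and DESeq2 called 2628 (median log2 0.20, camera adjusted p = 0.00096, and adjusted p = 0.593 with an estimated correlation). Mitochondrially encoded genes fell slightly (0 of 13 called, median -0.14, camera adjusted p = 0.0225, and adjusted p = 0.562 with an estimated correlation) and did not pass without NTC tumor 1 or 2 or Il1a-targeted tumor 2. Cytotoxic effector genes rose with 7 of 17 called higher and 1 lower (camera adjusted p = 3.53e-05, and 0.427 with an estimated correlation). Of the members, 13 were mostly free RNA, while Srgn (2282 and 1866 CPM) and Cx3cr1 (314 and 395 CPM) were not. The cytotoxic effector list in monocytes and macrophages did not pass with free RNA subtracted (adjusted p = 0.0588). It also did not pass with the automatic doublet threshold, which removed cells of Il1a-targeted tumor 2 alone. T cell markers stood at 51.8 ± 0.5 and 85.1 ± 11.8 CPM in this class. Neutrophil granule genes fell with 5 of 16 called lower and 1 higher (adjusted p = 7.04e-05, 0.330 with an estimated correlation, and 0.096 with free RNA genes left out), and 9 members were mostly free RNA. Lists that did not pass in this class were lipid-associated macrophage genes (1 higher and 2 lower of 17, camera adjusted p = 0.0777), complement (1 higher of 12, adjusted p = 0.121), T-cell checkpoint and exhaustion (adjusted p = 0.199), naive and memory T cell (adjusted p = 0.107), immediate early and heat shock (adjusted p = 0.151), nuclear oxidative phosphorylation (adjusted p = 0.0503) and antigen-presenting DC activation (2 higher of 14, adjusted p = 0.0969).

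In DCs, MHC class I genes rose as a list, with H2-Q4 called (log2 0.75) and 11 of 15 members higher adjusted over the list alone (median 0.30, camera adjusted p = 4e-06, and adjusted p = 0.467 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in DCs, with 1 of 28 called lower (median -0.17, adjusted p = 0.000309, and 0.467 with an estimated correlation). In T cells interferon gamma response genes rose with 5 of 20 called higher and 1 lower, 7 of them mostly free RNA (median 0.30, adjusted p = 9.96e-06, 0.369 with an estimated correlation, and 0.000621 with free RNA genes left out), and with free RNA subtracted the list had a change of -0.0 (adjusted p = 0.95). The type I interferon response list in NK cells rose with 2 of 21 members called higher, among them Ifit1 (log2 1.44), and 11 members mostly free RNA (adjusted p = 7.94e-06, 0.463 with an estimated correlation, and 0.0988 with free RNA subtracted). In B cells the MHC class II list rose with 0 of 10 called by edgeR, while 632 genes of the class stood at an unadjusted p under 0.05 and DESeq2 called 22 (median 0.55, adjusted p = 4.77e-05, and 0.330 with an estimated correlation), and 6 members were mostly free RNA. With free RNA subtracted that list turned in test direction (0.06, adjusted p = 0.69). B cell markers summed to 5794 ± 1738 and 8642 ± 866 CPM and macrophage markers to 14634 ± 3940 and 10278 ± 2106 CPM in B cells (exact permutation p = 0.2 and 0.3), where free RNA was estimated at 74.4% and 53.0% of counts.

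Cells left unnamed were 8.12% ± 2.93 of cells in NTC and 8.09% ± 6.22 in Il1a-targeted tumors. Part of them were the T cell subcluster mixed with macrophage RNA (1.065% and 0.591%). The rest were a cluster of low counts (2.65% and 2.39%), a cluster with T cell and macrophage markers (1.49% and 3.40%), a cluster led by the osteoclast genes Ctsk, Acp5 and Mmp9 (1.70% and 0.94%) and the keratin-positive cluster (1.22% and 0.764%). Plasmacytoid DCs were 0.380% and 0.439% of cells and mast cells or basophils 0.256% and 0.183%.

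Neutrophils, T cells, NK cells and B cells had 853 calls, with a gene counted once in each class that called it, and the free RNA estimate gave over 50% of the CPM difference for 68.3% of them. The share was 93.9% among the 593 calls mostly free RNA and 10.0% among the 260 others, a split made by the same estimate. T cells gave 749 of the 853 calls. Free RNA of the library, shared by its tumors, could thus account for many of these calls, though the test does not settle which. A difference between libraries and a biological change in the cells stay open for the others.

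The regulatory T cell share of T cells differed by -9.27 percentage points in Il1a-targeted tumors (-12.4 to -6.09 with each tumor left out), with 120, 90 and 47 mixed cells set aside in the NTC tumors and 65 and 42 in the others. Setting aside these cells is unlikely to have made the difference, since it was -18.4 points with them counted as regulatory T cells. A biological loss of regulatory T cells and a difference between libraries both stay open, and the exact permutation p of 0.2 does not exclude chance.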
